A study of Homo sapiens with 3 samples.

How the data were processed

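ChIP-seq was done in the NTera2 cell line with an in-house antibody against BEND3 (2 libraries) and with rabbit IgG (1 library). Per the labels' protocols, libraries were amplified for 10 cycles and sequenced for 101 cycles; the protocol text describes reads from one end of each fragment and also uses the term paired-end, so the read layout is uncertain. The submitters' processing notes name Novoalign, Picard 2.9.4, MACS2 and the hg19 (GRCh37) build, without roles or parameters. The threshold of peak calling is not given in the sources used here. Each BEND3 ChIP had its own peak list, called against IgG per the list names, and each list was matched to its ChIP by the title that its name holds. An IgG peak list was not used here, so no background list could be set beside the BEND3 lists.

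The lists hold 9 columns, with no header. The score of each peak, as deposited by the authors, was 10 times the last column with the decimals dropped in 100% of rows. The last column exceeded the one before it in 100% of rows, which −log10 p followed by −log10 q cannot do. With no header to settle the order or kind of values, no statistical meaning was given to these columns. The score was used to rank peaks within a list, and was set across lists in the correlation over shared regions and in a fit of the 2 lists' scores given among the additional observations. Aligned reads were not used here. The depth of each library is therefore unknown, and a longer list may reflect more reads, a stronger enrichment or both.

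Coordinates are given 1-based in hg19. Chromosome lengths and Giemsa bands of hg19 came from circlize 0.4.16, and 44 known genes of hg19 (147 transcripts on the main chromosomes) from the sample database of GenomicFeatures 1.54.1. Gene symbols were matched by gene identifier to a table of the GRCh38.p14 assembly, for 43 of the 44 genes; no coordinates were taken from that table. The planned share of peaks in exons and introns and the planned tests of gene lists need a full hg19 annotation and were not run.

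Overlap of at least 1 bp was counted with bedtools 2.31.1. Chance overlap and the number of neighbouring peaks by chance came from 10000 random placements of peaks on their own chromosomes with widths kept, which could not leave out gaps of the assembly. Medians and correlations were tested with 100000 resamples. Peaks per chromosome were tested by Fisher's exact test on 1 kb windows that hold a peak midpoint, two-sided, with Benjamini-Hochberg adjustment over chromosomes. The threshold was 0.05. Intervals are at 95% and cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

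The rule for the regions named in the text was fixed before the data were examined: the 10 peaks of each list with the highest score and the 20 shared regions with the smallest sum of ranks. Alternatives fixed at the same time were peaks at or above the median score, other minimum overlaps, equal list lengths, autosomes and X only, merging of peaks within 1 kb, other distances, means in place of medians and leaving out either ChIP. Chosen after seeing the data were the tests of peak width at shared regions, Giemsa bands, chromosome ends and chromosome arms, the sample of 44 genes, 2 other models of chance placement, and the removal of peaks within 50 kb of a chromosome end, within 1 Mb of a centromere or in a variable band.

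The functions were tested on simulated data. In 40 random lists of 216 peaks, the overlap test gave p under 0.05 in 0, the grouping test in 1 and, over 40 random splits of the scores, the test of medians in 3. Chance overlap of the 2 lists averaged only 0.0948 regions, so the 0 of the overlap test was nearly fixed in advance and tells little. Of 60 planted shared peaks 60 were found, which was certain because they were placed at starts of replicate 2 peaks. The result (permutation p = 0.002) was the smallest that the fewer placements used there can give. The random lists were placed as in the model of chance, so these checks do not cover peaks that favour some regions.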

Results

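Chromatin of NTera2 cells, a human embryonal carcinoma line of testicular origin that is widely used as a model of pluripotent cells, was immunoprecipitated with an antibody against BEND3, a BEN-domain protein, and sequenced. The series title names transcriptional repression by BEND3 as its subject, and the question the design addresses is where in the genome the antibody enriched DNA. There were 2 BEND3 ChIP libraries (replicates 1 and 2) and 1 rabbit IgG library, which served as the control of both. The data used here were 2 peak lists, 1 per BEND3 ChIP, in hg19 coordinates. Read numbers per library are not given in these lists, so the depth behind each peak is unknown. The labels do not say that the 2 ChIPs came from separate cultures, so their agreement may be partly technical. The score of each peak is the authors' own value and was used to rank peaks within a list. Test results over peaks describe these 2 lists, because peaks are not independent replicates.

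The strongest peak of both lists lay at the tip of the short arm of chromosome 5, at 10025 to 11783 in replicate 1 (score 3200) and at 10013 to 11796 in replicate 2 (score 3590). Next in both lists came the tip of the long arm of chromosome 12, at 133841523 to 133841875 in replicate 1, with scores of 2324 and 2620 in replicates 1 and 2. The tips of the long arms of X (155260021 to 155260383 in replicate 1) and Y (59363026 to 59363403) were also among the 5 strongest peaks of each list. The tips of X and Y carry pseudoautosomal sequence, which both chromosomes share, so their peaks are not independent of each other. Away from chromosome ends, the strongest peak of both lists lay in band 2q37.2, at 237088175 to 237088571 in replicate 1, with scores of 1782 and 2571. It was followed in replicate 1 by 11p15.5 (1691719 to 1692048, score 1193) and 19p13.11 (18392661 to 18392939, score 1193). In replicate 2 it was followed by 9q22.33 (100174069 to 100174441, score 2193) and 1q23.3 (161435061 to 161435646, score 1958). Of the 10 strongest peaks of replicate 1, 10 overlapped a replicate 2 peak, and 9 of the 10 strongest of replicate 2 overlapped a replicate 1 peak. The exception, in Yq12 at 58857678 to 58858177, had a score of 1885 in replicate 2.

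Replicate 1 had 216 peaks and replicate 2 had 1118. The peaks covered 81.2 kb in replicate 1 and 522 kb in replicate 2, or 0.00262% and 0.0169% of the assembly. They were narrow, with a median width of 302 bp in replicate 1 (quartiles 238 and 427 bp) and of 346.5 bp in replicate 2 (quartiles 256 and 586 bp). The lowest scores were 254 in replicate 1 and 241 in replicate 2. Together the lists named 1138 regions, of which 20 were in replicate 1 alone, 196 in both and 922 in replicate 2 alone. Without replicate 2 the number of regions was 216, so that library set most of the total.

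Nearly every region of the shorter list overlapped one of the longer list by at least 1 bp. A replicate 2 peak overlapped 196 of the 216 replicate 1 peaks by at least 1 bp, a share of 90.7% (95% exact binomial interval 86.1 to 94.3%). These made up 17.5% of the replicate 2 list (15.3 to 19.9%). Random placement of the replicate 2 peaks on their own chromosomes gave a mean of 0.0948 shared regions and at most 3 in 10000 placements (one-sided permutation p = 0.0001, the smallest these placements can give). Both lists were called against the same IgG library, and part of the excess over chance may come from that shared control. With the longer list reduced to its 216 strongest peaks, 112 regions were shared. When at least 50% of both peaks had to overlap, 139 of the 216 replicate 1 peaks were shared (64.4%).

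Shared peaks were the stronger ones in each list. In replicate 1 the median score was 472.5 for the 196 shared peaks and 336.5 for the 20 others (difference 136, two-sided permutation p = 0.0082). That difference was 67 when at least 50% of both peaks had to overlap (permutation p = 0.016), and 222 between means (p = 0.012). The replicate 2 medians were 606.5 for the shared peaks and 377 for the 922 others (difference 229.5, permutation p = 1e-05, the smallest that 100000 resamples can give). Adjusted over the 2 lists by the Benjamini-Hochberg method, the p-values were 0.0082 and 2e-05. In the highest score decile of the replicate 2 list 72 of 111 peaks were shared, or 64.9% (95% exact interval 55.2 to 73.7%), and in the lowest decile 1 of 112. All 21 peaks in the highest decile of replicate 1 were shared, and 16 of 22 in its lowest.

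**Figure D1:**
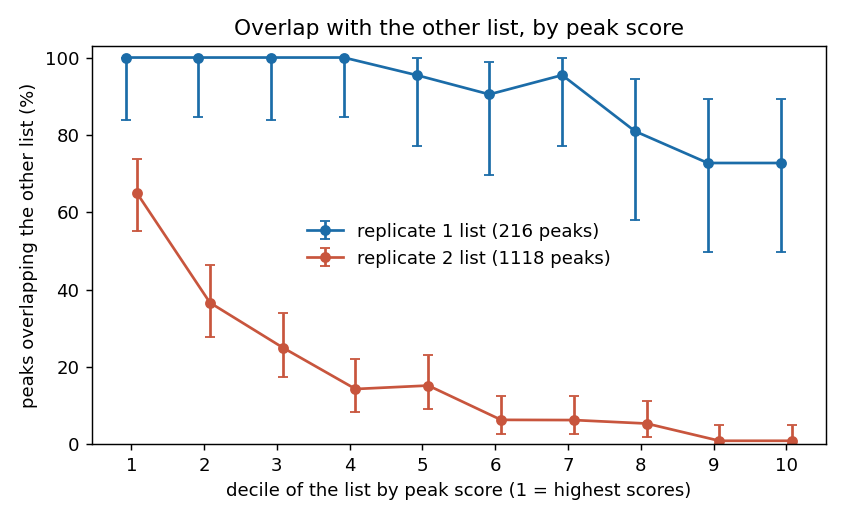
Share of peaks (%) that overlap a peak of the other list, by decile of the list ranked by score (1 holds the highest scores), with 95% exact binomial intervals as bars. Replicate 2 falls from 64.9% in its highest decile to 0.893% in its lowest, and replicate 1 from 100% to 72.7%.

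Across the 196 shared regions, Spearman's rho of the scores was 0.79 and Pearson's r was 0.92 (permutation p = 1e-05 for each, the smallest possible). For peak width in place of score, rho was 0.439. Without the 2 regions farthest from the median score of replicate 1, r was 0.895. These are correlations across regions of one pair of libraries, and regions are not independent replicates. Both score sets were made against the same IgG library, so the value without any BEND3 signal need not be 0. That value is not known from these lists, and the p-values test against 0. At shared regions the replicate 2 peak was wider in 172 cases and narrower in 23. The median ratio of widths within a region was 1.35, replicate 2 over replicate 1 (sign-flip permutation p = 1e-05 for the mean log ratio, the smallest possible). Median widths were 301 bp in replicate 1 and 493 bp in replicate 2.

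**Figure D2:**
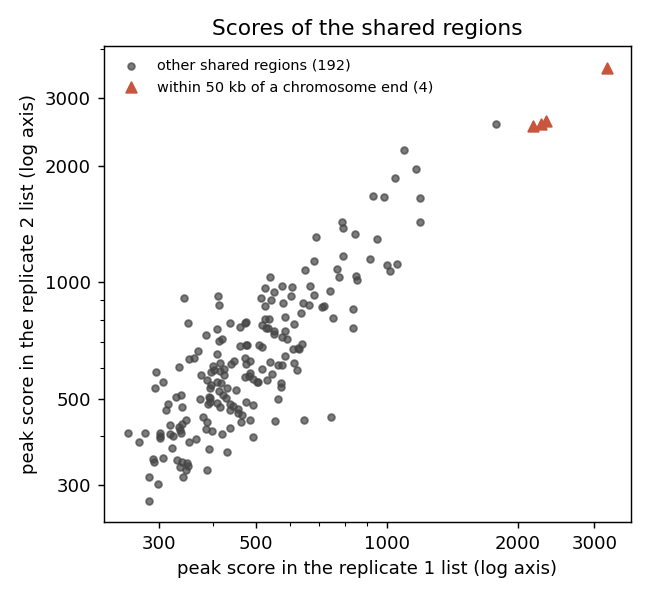
Peak score in replicate 1 (horizontal, log axis) against that in replicate 2 (vertical, log axis) for the 196 shared regions, with triangles for the 4 regions within 50 kb of a chromosome end. The triangles stand at the upper right, and Spearman's rho over all the points is 0.79.

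The 20 shared regions with the highest joint rank were spread over 11 chromosomes. Of these regions, 4 lay at the chromosome ends named above, 4 on chromosome 1 and 3 on the short arm of chromosome 19. Those on chromosome 19 were at 18392661 to 18392939 (19p13.11), 2841031 to 2841309 (19p13.3) and 8942741 to 8943051 (19p13.2) in replicate 1. Those on chromosome 1 were in 1p36.23 (7765007 to 7765509), 1q21.3 (154974000 to 154974383) and, with 2 regions, 1q23.3 (161420346 to 161420825 and 161435361 to 161435611). Chromosome 9 held 3, in 9q22.33 (100174109 to 100174418), 9q33.2 (123964223 to 123964530) and 9q34.11 (131182432 to 131182765). The others included 12p12.3 (19592319 to 19592600), 17q25.3 (79479930 to 79480273), 2q37.3 (242674057 to 242674976) and 10q26.2 (130262651 to 130262982). Giemsa-light bands, which are known to be gene-rich, held 14 of the 20. They also held 71.3% of all replicate 1 peaks and make up 42.2% of the genome, so that count is not particular to these regions.

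Chromosome 19, the chromosome known for its high gene density, had the greatest excess of peaks over its length. It held 17 peaks of replicate 1, 4.12 times the number its length predicts (95% exact Poisson interval 2.40 to 6.60, Fisher exact test, Benjamini-Hochberg adjusted p = 2.8e-05). In replicate 2 it held 69, or 3.23 times the prediction (2.51 to 4.09, adjusted exact p = 1.2e-15). Chromosome 1 held 35 and 174 peaks, 2.01 and 1.93 times the prediction (adjusted exact p = 0.00093 and 1.2e-15). Besides these, chromosomes 16, 17 and 21 held more peaks than predicted in both lists. Chromosomes 12 and 20 passed the threshold in replicate 2 alone, though their ratios to prediction were of similar size in both lists. These were 1.71 and 1.57 for chromosome 12 and 1.59 and 1.58 for chromosome 20, in replicates 1 and 2. The difference between lists was not tested there. Chromosome X held 3 and 9 peaks, 0.277 and 0.16 times the prediction (adjusted exact p = 0.034 and 4.1e-14), and chromosome 3 was also low in both lists. The prediction uses length alone, and the number of copies of each chromosome was not measured. A high or low call, that of X included, need not mean a different number of bound sites per copy. With centromeric, variable and stalk bands left out, chromosomes 4, 5 and 8 were low in both lists too. Among peaks at or above the median score, 3 of the 5 high and 0 of the 4 low calls of replicate 1 were kept. In replicate 2, 5 of the 7 high and 5 of the 8 low calls were kept; chromosome 17 lost its call in both lists, as did chromosome 3.

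**Figure D3:**
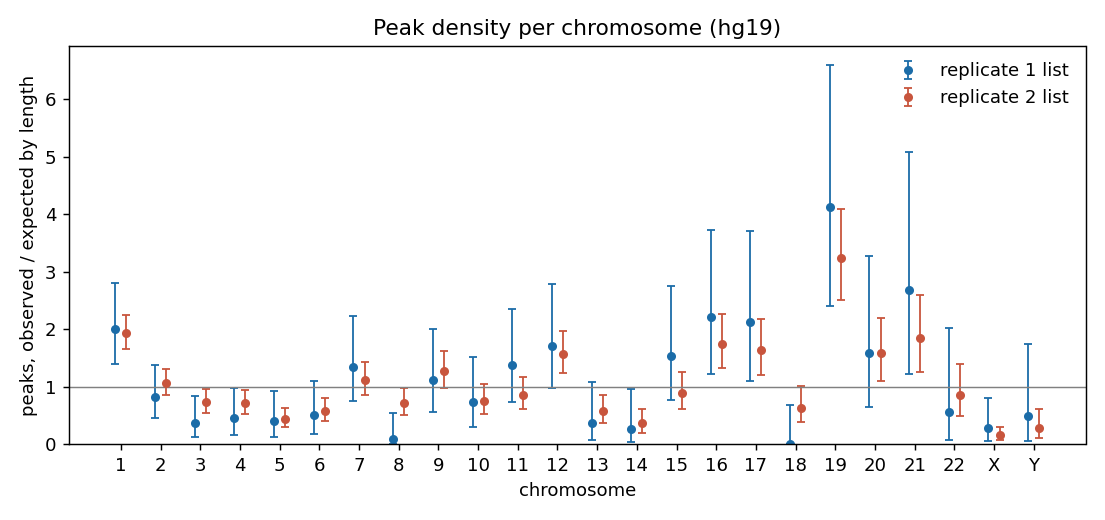
Observed over expected number of peaks per chromosome (expected from hg19 length), replicate 1 and replicate 2, with 95% exact Poisson intervals as bars and a line at 1. Chromosome 19 stands highest, at 4.12 in replicate 1 and 3.23 in replicate 2.

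Peaks lay in groups more often than random placement over whole chromosomes gives, which makes no allowance for an excess of peaks in gene-rich bands. In replicate 2, 58 peaks had another within 10 kb, against a mean of 11.1 in 10000 placements (one-sided permutation p = 0.0001, the smallest possible). They formed 25 groups, of which 23 were pairs. The largest was a row of 8 peaks in 1q23.3, from 161412923 to 161440904 on chromosome 1. Its peak starts were spaced 3.68 ± 0.0672 kb apart (SD over 7 steps), and narrow peaks of 553 to 722 bp alternated with wide peaks of 1536 to 2209 bp. The sequence of the row was not examined, so its peaks may lie on copies of 1 sequence and not be independent. Replicate 1 had 4 peaks in the same stretch. They were its only peaks with a neighbour within 10 kb (mean by chance 0.485, permutation p = 0.024), so this test rests on that stretch alone. With a distance of 1 kb, replicate 1 had 0 such peaks (permutation p = 1).

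**Figure D4:**
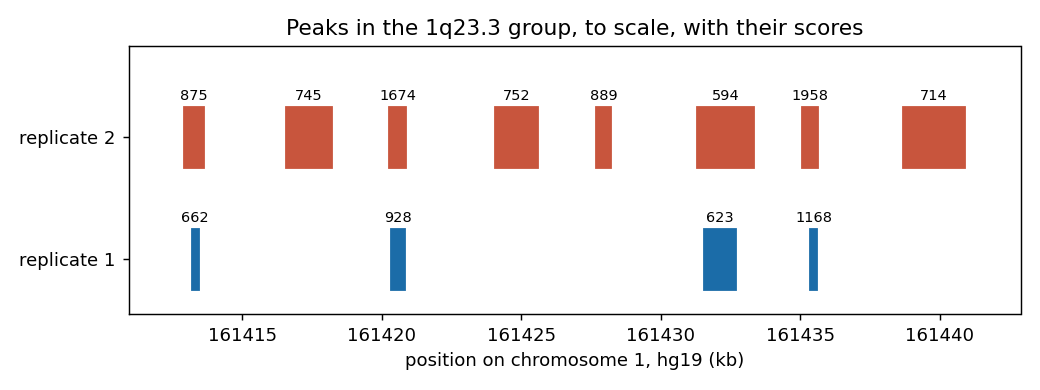
Peaks of replicate 1 and replicate 2 in the 1q23.3 group on chromosome 1 (hg19 position in kb), drawn to scale as boxes with their scores above. Replicate 2 has 8 peaks at steps of 3.63 to 3.8 kb, and replicate 1 has 4, each of them under a replicate 2 peak.

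A full hg19 annotation was not used here, so genes were assigned only for 44 known genes with 95 start sites, a sample whose selection is not known. CERCAM, on the plus strand of chromosome 9, was the one gene of this sample with a peak within 1 kb of a start site in both lists. Its peak at 131182432 to 131182765 (score 846 in replicate 1, 1331 in replicate 2) overlapped 2 internal start sites, the first at 131182466, and the first exon of that transcript. ETV6, which encodes a transcriptional repressor of the ETS family, had a replicate 2 peak at 11801942 to 11802989 on chromosome 12 (score 450) that overlapped its start site at 11802788 and its first exon. ETV6 was named after its values were seen. In replicate 2, 2 of the 44 genes had such a peak against 0.0726 by random placement (one-sided permutation p = 0.0024), and in replicate 1, 1 gene against 0.014 (p = 0.014). The replicate 1 count rests on a single gene, and with a 5 kb window its permutation p was 0.055. Placement was over whole chromosomes, so these p-values do not separate nearness to start sites from an excess of peaks in gene-rich bands.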

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

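Of 67 alternative values, 53 stayed on their side of the threshold or, for counts, within 1.5 times the reported count. None reversed a call, but a reversal was defined only for results with a sign, such as differences and correlations, and not for counts. Among these 53, the replicate 1 difference between shared and other peaks moved from 136 to 67 with 50% overlap and to 222 with means, and rho from 0.789 to 0.439 with width. Keeping peaks at or above the median score, which removes peaks by construction, gave 108 and 561 peaks for replicates 1 and 2, 106 shared regions, 34 grouped peaks in replicate 2, and 3 chromosomes above and 0 below prediction in replicate 1. At equal list lengths 112 regions were shared. Leaving out either ChIP gave 216 to 1118 regions in either list. Peaks with a neighbour within 1 kb numbered 0 in replicate 1 (permutation p = 1) and 8 in replicate 2 (p = 0.009), and within 100 kb 12 (p = 0.024) and 243 (p = 0.0001, the smallest possible). A 5 kb window at start sites left 1 gene in replicate 1 but ended the call (permutation p = 0.055), as the wider window raises the chance count. Added after seeing the data, a window of 200 kb at chromosome ends gave 19 peaks in replicate 2. Also added then, removing centromeric, variable and stalk bands kept all 9 chromosome calls of replicate 1 and all 15 of replicate 2. It added low calls for chromosomes 4 and 5 in replicate 1 (adjusted exact p = 0.042 and 0.041) and, in replicate 2, a low call for 8 (0.027) and a high call for 9 (0.024). Removing peaks near chromosome ends, centromeres and variable bands ended the call of chromosome 17 in replicate 1, leaving 4 above prediction. Among peaks at or above the median score, replicate 2 had 5 chromosomes above and 6 below prediction in place of 7 and 8. No paired analysis was possible because the groups share fewer than 2 replicate numbers. The tests of gene lists, with their 5 kb alternative, were not run; for protein-coding genes, the 40 sampled genes with a coding sequence were used. Unknown depth limits every absence from a list: a region in replicate 2 alone was not detected in replicate 1 at its depth and threshold.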

Other observations

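The results and tests of this part were chosen after the data had been seen, except the 10 kb distance that defines groups of peaks and the 5 kb window at start sites. Giemsa-light bands held 71.3% of the replicate 1 peaks (95% exact interval 64.8 to 77.2%) and 66.4% of the replicate 2 peaks (63.5 to 69.1%), against 42.1% and 42.5% by random placement on the same chromosomes (one-sided permutation p = 0.0001 for each, the smallest possible). Counting only peaks in light bands, the short arm of chromosome 19 was the densest of 43 arms in both lists, with 1.03 peaks per megabase of light band in replicate 1 and 3.36 in replicate 2 (Benjamini-Hochberg adjusted exact binomial p = 3.3e-06 and 2.9e-15). The long arm of X was the sparsest in replicate 2, with 2 such peaks and 0.0491 per megabase (adjusted exact p = 7.6e-07). The number of copies of X was not measured. In 1q42.13, replicate 2 had a group of 4 peaks from 228751032 to 228762157 on chromosome 1 and, 11.8 kb further on, a pair from 228773976 to 228776808. The scores of these 6 peaks were 587 to 776, and replicate 1 had 0 peaks there. Upstream of ZP3, a gene for a protein of the egg coat, replicate 2 had a peak at 76022618 to 76023072 on chromosome 7. The nearest start site among the 44 sampled genes was 3769 bp away, and other genes were not looked at.

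Within 50 kb of a chromosome end lay 4 peaks of replicate 1 and 12 of replicate 2, against 0.179 and 0.924 by random placement (one-sided permutation p = 0.0001 for each, the smallest possible). All 4 in replicate 1 and 10 in replicate 2 lay 10054 to 10904 bp from the end of the assembly coordinates. Gaps of the assembly were not located, so how near these peaks lie to the first sequenced base is not known. The chance counts also include unsequenced bases. A candidate explanation of the end peaks is repeated sequence collapsed in the assembly, which could also raise peaks near centromeres or in variable bands. Of those 21 replicate 2 peaks 19% were among the 112 with the highest scores (95% exact interval 5.45 to 41.9%), against 9.4% of the 1085 others (Fisher exact p = 0.13). This comparison cannot decide, since the peaks are few and place only stands in for repeats. No sequence was examined, and the others may hold repeats too, such as the evenly spaced row of peaks on chromosome 1. The X and Y tips share pseudoautosomal sequence, so their peaks at the long-arm ends, and a pair near the short-arm tips (1572373 to 1573171 on X and 1522445 to 1523148 on Y in replicate 1), may each be 1 sequence counted 2 times; with Y-tip peaks left out, 3 and 11 end peaks remain in the lists (permutation p = 0.001 and 0.0001). Whether the antibody binds repeats at chromosome ends was not tested. The only control was IgG, and the design has no ChIP with this antibody from cells that lack BEND3.

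Some strong replicate 2 peaks were absent from replicate 1: 1 of the 10 strongest, 10 of the 50 strongest (20%, 95% exact interval 10.0 to 33.7%) and 31 of the 100 strongest. Among the 112 highest-scoring peaks of replicate 2, 6 of the 10 near ends, centromeres or variable bands were absent (60%), against 34 of the 102 elsewhere (33.3%, Fisher exact p = 0.16). These are too few to decide whether place matters, and the 34 elsewhere are not covered by it. A lower yield in replicate 1 also stays open: one common relation between the scores, fitted with its scatter and the lower limit of replicate 1 to the other 1068 peaks, leaves 6.21 of the 50 strongest absent (95% range 2 to 12), and the 10 observed lie within it. That range rests on a fitted scatter of 0.702 natural-log units, and most of the fitted peaks were themselves absent from replicate 1. The fit also replaced an earlier comparison with a hand-picked bound, which had gone against lower yield. It therefore cannot decide. No biological explanation was tested, since both ChIPs belong to 1 group.

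The short arm of chromosome 12 ranked 2 among 43 arms in replicate 2, with 37 peaks in bands of any stain, 2.84 times the number its length of light band predicts (adjusted exact binomial p = 2.8e-07). Gain of 12p is common in testicular germ cell tumours, and extra copies of 12p in the cell line could raise the number of peaks called there, in both lists. The number of all peaks on the arm per megabase of light band was 2.61 times as high on 12p as on 12q in replicate 2 (95% exact interval 1.62 to 4.21) and 0.92 times in replicate 1 (0.216 to 3.03, exact binomial p = 1), with 4 peaks on 12p, too few to decide. Counting only peaks in light bands, the ratios were 2.75 (1.55 to 4.88) and 1.03 (0.176 to 4.3). The split between 12p and 12q was not shown to differ between the lists (Fisher exact p = 0.1). That test counts the lists as independent, but the 4 replicate 1 peaks on 12p all overlapped replicate 2 peaks, so it cannot decide. Copy number was not measured here.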
